A study of Homo sapiens with 11 samples.

How the data were processed

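RNA-seq counts of 9 libraries of LX-2 cells (PBS, HIV-1 and HIV-1+LTA, 3 libraries each, 24 h) and a list of ChIP-seq peaks of HIV-1-treated cells were used. Per the submitters' processing notes, reads were handled with fastp, STAR, SAMtools and HTSeq for RNA-seq and Bowtie2, bedtools and deepTools for ChIP-seq on hg19; tool versions, the strand setting, the peak caller's threshold, the antibody and the ChIP control are not given. The authors deposited raw counts per gene symbol, which are whole numbers that sum to 50.6 to 90.6 M per library. The authors also deposited a DESeq2 table with a mean signal (counts divided by size factors and averaged over libraries), the log2 fold change and its standard error in log2, a Wald score, a p-value and an adjusted p-value. That deposited table does not name its comparison. It holds the 19990 genes with a total count of at least 10, and gives 236 genes past an adjusted p of 0.05 (118 higher, 118 lower); 7751 genes have no adjusted p. Its log2 fold changes were checked against fits of the counts: a DESeq2 fit with batch and group gave all of them within 0.01 for HIV-1+LTA against PBS, while the correlation was 0.502 for each of the other comparisons. The deposited peak list has 4 columns (chromosome, start, end and name) and no value per peak.

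The count file names 35303 genes, 25265 of them with any count. Genes were kept by filterByExpr with the groups, which left 16117. The test was the edgeR 4.0.16 quasi-likelihood test on raw counts with TMM scaling, 1 fit over all 9 libraries with group only, and Benjamini-Hochberg adjustment, a gene passing at an adjusted p below 0.05. Comparisons were HIV-1 against PBS, HIV-1+LTA against HIV-1 and HIV-1+LTA against PBS. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), each with and without the replicate block, other scalings and filters, a fit of only the 6 libraries compared, a fold limit, and leaving out each library. R was 4.3.3. Log2 CPM used TMM and a prior count of 2.

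The replicate number is the batch number per the labels, so the numbers pair libraries of different groups. A check of this pairing correlated each library's deviations from its group: same-batch pairs reached 0.705 to 0.917, and 6 of 9 libraries correlated best with their own batch in both other groups. Pairs of batch 3 gave the highest values, 0.905 to 0.917. In batches 1 and 2 same-batch pairs ran from 0.705 to 0.784. Pairs of different groups between batches 1 and 2 ran from 0.684 to 0.764. By this measure batch 3 stands apart, but it does not settle the pairing within batches 1 and 2. No 2 libraries were copies of 1 another: the chi-square between pairs, divided by its expectation from counting noise, was at least 2.83. By this chi-square the pairs within batch 1, at 2.83 to 3.29, were closer than any between batches 1 and 2, at 6.19 to 16. The libraries of batch 1 thus hold together. Pairs within batch 2, at 6.31 to 18, overlapped those between the batches, so the pairing of batch 2 stays unsettled. Blocked values stand beside the others wherever they change a call. DESeq2 with the replicate block on genes with a total count of at least 10, the setting that gives the deposited table, was added after the edgeR fit had been seen to call no gene.

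In all, 24 gene lists were fixed, for chemokines, innate immune signalling, HIV-1 host factors, stellate cell and matrix genes, signalling, stress, metabolism, RNA quality and other cell types; 23 had at least 5 tested members. They were tested with camera (limma, preset inter-gene correlation 0.01, two-sided, adjusted over the lists of a comparison), with camera with an estimated correlation, and with fry, which tests whether a list's genes move on balance one way and compares them with no other genes. The lists, the tests and the rule for named genes were set before the data were examined. By that rule CXCL8 is always named; among passing genes with a mean of at least 1 CPM and the same direction in all 3 batches, the 10 highest and 10 lowest log2 fold changes are named (pseudogenes, small RNAs, antisense and uncharacterised loci are counted but not named), and where none passes the 5 genes with the lowest p; for a list with passing members up to 4 are named, and for one without at most 2. Afterwards the same rule was applied to the DESeq2 fit with the block, for genes also tested in edgeR. Within-batch differences are differences of log2 CPM between the libraries of a batch. Correlations across genes used genes with a mean of at least 10 CPM.

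The tests were checked on counts simulated with the spread of these libraries (16117 genes, HIV-1+LTA against HIV-1). Of simulated 1.5-fold, 2-fold and 4-fold changes, edgeR without the block recovered 4.48%, 28.4% and 74.2%, edgeR with it 83.6%, 100% and 100%, and DESeq2 with it 82.1%, 100% and 100%. False calls numbered 0, 10 and 14, and 0, 0 and 1 when nothing was changed. A simulated list raised by 0.5 on the log2 scale passed camera with an estimated correlation, at an adjusted p of 0.000181 without the block and 0.00512 with it. These simulations raise every batch alike and draw each gene independently of the others. In the data the interferon-stimulated list had an estimated inter-gene correlation of 0.0876 without the block and 0.423 with it. The simulated list therefore does not show how readily a list in these data would pass camera with an estimated correlation.

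The deposited peaks were placed on protein-coding genes of the GENCODE annotation for hg19: within 1 kb of a transcription start, else exon, intron or outside, with 100 random placements for comparison. Genes within 10 kb of a peak were compared with called genes by Fisher's exact test. Repeated lines of the list, 12 of 166, were counted once. Counts assigned to genes with close paralogs or pseudogenes, among them the histone, IFITM, MHC and ubiquitin genes, may include reads of their relatives. No column of counts was left out. Some genes that the rule would name are not reported here. The PBS ChIP library was not used here.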

Results

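RNA-seq was done on LX-2 cells, an immortalised line of human hepatic stellate cells, the liver cells that lay down scar matrix when activated. Cells received PBS, HIV-1BaL at a multiplicity of infection of 0.1, or the same virus with lipoteichoic acid (LTA, a cell wall component of Gram-positive bacteria sensed mainly through TLR2) at 1 ug per ml. Each group had 3 libraries taken at 24 h, 1 from each of 3 batches. The libraries held 50.6 to 90.6 M counts, 9 libraries in all. No library had LTA alone, so the effect of LTA could be compared only in cells with virus. ChIP-seq was done on 1 PBS and 1 HIV-1 library, whose titles name Lx2 cells while their labels name the cell line Lx3 and Lx5; they were read here as LX-2, which was not tested. The labels give no antibody, and the 1 peak list used here is for HIV-1.

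The 3 libraries of batch 3 stood apart from the other 6 whatever the treatment. The first principal component held 81.6% of the variance and separated batch 3 from batches 1 and 2. With batch means removed, the first component (31.4%) separated HIV-1+LTA replicates 2 and 3 from the other 7 libraries, and HIV-1+LTA replicate 1 lay beside its PBS and HIV-1 partners.

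**Figure D1:**
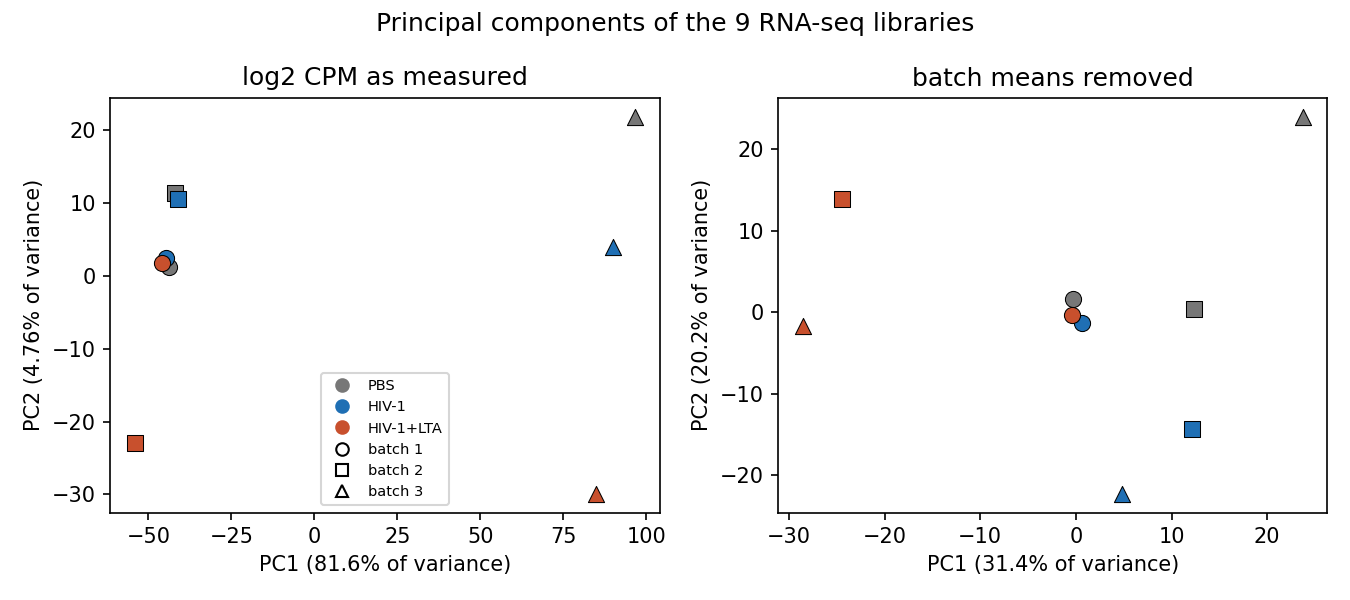
Principal components of log2 CPM (counts per M counts of the library) of the 9 RNA-seq libraries, as measured (left) and with each gene's batch mean removed (right); axes are component scores, colours the groups, symbols the batches. The first component on the left holds 81.6% of the variance and parts batch 3 from the rest; on the right, HIV-1+LTA replicates 2 and 3 score -24.5 and -28.5, and the 3 libraries of batch 1 lie near 0.

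The series asks how HIV-1 bears on the response of stellate cells to Gram-positive products through IL-8, the neutrophil-attracting chemokine encoded by CXCL8 (hg19 chromosome 4, 74606236 to 74609433). CXCL8 was measured at 3.37 ± 0.691 CPM with PBS, 3.9 ± 0.639 CPM with HIV-1 and 5.1 ± 1.28 CPM with HIV-1+LTA (SD, n = 3 each), from 186 to 456 counts per library. Its log2 fold change was 0.21 (SE 0.257) for HIV-1 against PBS, 0.39 (SE 0.257) for HIV-1+LTA against HIV-1 and 0.60 (SE 0.257) for HIV-1+LTA against PBS. None passed in edgeR, where the unadjusted p was 0.435, 0.167 and 0.0476 and the adjusted p was 1 in each. With the replicate block in edgeR the unadjusted p was 0.344, 0.0819 and 0.0138, and the adjusted p was 0.951, 0.388 and 0.217. The authors' deposited table gives CXCL8 a log2 fold change of 0.58 (SE 0.211) for HIV-1+LTA against PBS with a DESeq2 adjusted p of 0.11. Within batches 1, 2 and 3 the HIV-1+LTA minus PBS difference was 0.46, 1.31 and -0.01, HIV-1+LTA minus HIV-1 was 0.62, 0.50 and -0.01, and HIV-1 minus PBS was -0.16, 0.81 and 0.00488 (log2 CPM).

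**Figure D2:**
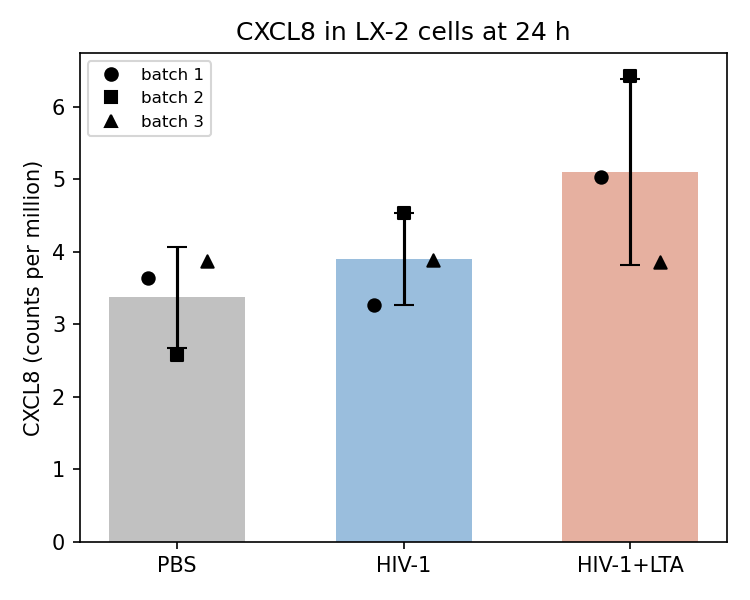
CXCL8 in CPM for each treatment at 24 h; bars are means, error bars the SD of 3 libraries, and points single libraries with their batch. HIV-1+LTA has the highest mean (5.1 CPM), while the 3 libraries of batch 3 lie between 3.86 and 3.89 CPM.

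HIV-1 against PBS asks what the virus did at 24 h, and few genes passed. In DESeq2 with the replicate block, 3 genes passed: IGFBP5, a secreted binder of insulin-like growth factors, fell, MRPL23, a protein of the mitochondrial ribosome, rose, and ANGPTL5, an angiopoietin-like secreted protein, fell. IGFBP5 had a log2 fold change of -0.37 (SE 0.0698, DESeq2 adjusted p 0.00174) and was lower in 3 of 3 batches. In edgeR with 1 library left out it ran from -0.63 to -0.06, the smallest fall coming without PBS replicate 2. In the same DESeq2 fit IGFBP5 passed higher in HIV-1+LTA against HIV-1, which shares the HIV-1 libraries, and was not called in HIV-1+LTA against PBS. The other 2 were named after their values were seen: MRPL23 had 414 and 423 counts in HIV-1 replicates 2 and 3 and at most 9 in each other library, and ANGPTL5 had counts in only 2 libraries, 3 in PBS replicate 2 and 8 in HIV-1+LTA replicate 1. These 2 reached 2-fold, and the median absolute log2 fold change of the 3 calls was 5.41. The genes with the lowest p in edgeR, none of which passed, were ATP8 (-0.23, SE 0.0889) and ND6 (-0.25, SE 0.102), both encoded by mitochondrial DNA, the peroxisome assembly factor PEX2 (-0.29, SE 0.12), the NF-kB target TRAF1 (0.63, SE 0.271) and the kinase CDKL3 (0.41, SE 0.185).

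Among the gene lists, the mitochondrially encoded genes stood lower with HIV-1 as a set: all 13 had a negative log2 fold change, with a median of -0.21. Camera gave this list an adjusted p of 2.1e-13, and adjusted p = 0.265 with an estimated correlation; its median was -0.05, -0.43 and -0.13 in batches 1, 2 and 3. Replication-dependent histone genes stood higher (16 of 18 above 0, median 0.19, camera adjusted p 2.39e-05; adjusted p = 0.275 with an estimated correlation), with H4C5 at 0.55 (SE 0.329). MAPK feedback genes, which damp growth factor signalling, stood higher too (17 of 21 above 0, median 0.11, camera adjusted p 0.00736; adjusted p = 0.275 with an estimated correlation), with the phosphatases DUSP5 at 0.26 (SE 0.13) and DUSP7 at 0.15 (SE 0.095). So did chemokines and cytokines (18 of 21 above 0, median 0.20, camera adjusted p 0.0135; adjusted p = 0.275 with an estimated correlation), with CXCL3 at 1.01 (SE 0.506) and IL1A at 0.54 (SE 0.312). In batch 1 the medians of the histone, MAPK feedback and chemokine lists were -0.02, -0.02 and -0.04. With the replicate block in camera 6 lists passed, the added ones being immediate early genes, higher at an adjusted p of 0.0152, and cytosolic ribosomal protein genes, lower at an adjusted p of 0.0204; with the block and an estimated correlation the adjusted p = 0.631 and 0.754. No member of any list passed over all genes in DESeq2 with the replicate block; adjusted over the list alone, 12 of 13 mitochondrially encoded genes were lower and 1 histone gene was higher in that fit, against 7 lower in edgeR with the block and 0 in edgeR without it.

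The interferon-stimulated genes were close to PBS in cells with HIV-1 (median 0.01, 22 of 38 above 0, camera adjusted p 0.362). So were the NF-kB target genes (median 0.04, camera adjusted p 0.206) and the activated stellate cell and matrix genes (median -0.05, camera adjusted p 0.607). In the last list ACTA2, the smooth muscle actin of activated stellate cells, was at -0.43 (SE 0.297), with 0.44, -0.70 and -0.78 in batches 1, 2 and 3. Across all genes edgeR called 0 of 16117 in this comparison, with 42 at an unadjusted p below 0.05, where 805.8 are expected if no gene changed. Without the block the batch differences stay in the spread, so this fit is too strict and its 0 calls do not show a lack of effect. edgeR and limma-voom with the replicate block also called 0 (678 and 725 below that p), and DESeq2 without it called 1.

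HIV-1+LTA against HIV-1 asks what LTA added in cells with virus. The calls named here are those of DESeq2 with the replicate block, while edgeR and limma-voom with the block called 0 genes. In DESeq2 with the block 10 of 38 measured interferon-stimulated genes rose and 28 did not pass, and the list's median was 0.01 in batch 1. Among the 10 were PSMB9, an immunoproteasome subunit (0.66, SE 0.137), DDX60, a helicase of antiviral sensing (0.64, SE 0.121), PARP14, an ADP-ribosyltransferase (0.43, SE 0.0982), and IFI16, a DNA sensor (0.39, SE 0.092). The HIV-1 restriction factors TRIM22 (0.64, SE 0.143) and IFITM2 (0.48, SE 0.11) rose in the same fit, and so did CD14, the co-receptor that hands bacterial ligands to Toll-like receptors (0.56, SE 0.165). CD14 was not called in HIV-1+LTA against PBS. In batch 1 it was at 7.71 CPM with PBS, 5.78 with HIV-1 and 7.81 with HIV-1+LTA. In batches 2 and 3 HIV-1+LTA was above both other groups. Of 26 TGF-beta targets 2 fell and 24 did not pass; the 2 were SMAD7, an inhibitor induced by TGF-beta (-0.55, SE 0.112), and SNAI2, a transcription factor of mesenchymal cells (-0.40, SE 0.108). Of 25 immediate early genes 2 fell and 23 did not pass; the 2 were the phosphatase DUSP1 (-0.45, SE 0.117) and the transcription factor KLF2 (-0.65, SE 0.181).

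Among the genes that the naming rule covers (a mean of at least 1 CPM, the same direction in 3 of 3 batches, tested in edgeR, and no pseudogene, small RNA, antisense or uncharacterised locus), the largest rises in that fit were DTNA (a dystrophin-associated protein) at 1.52 (SE 0.382), MGP (an inhibitor of matrix calcification) at 1.41 (SE 0.305), GASK1B at 1.10 (SE 0.215), CLCA2 at 1.08 (SE 0.297) and PPL (a plakin of cell junctions) at 1.05 (SE 0.268). GNG7, SEMA6D, AKR1C3, FAIM2 and GNG4 followed, from 0.97 down to 0.90. The largest falls among the covered genes were DAW1 (-1.08, SE 0.295), NFATC2, a calcium-regulated transcription factor (-0.90, SE 0.168), the potassium channel gene KCNQ5 (-0.72, SE 0.144) and HES1, a Notch target (-0.69, SE 0.203). KLF2, BCYRN1, XYLT1, NPR3, SMAD7 and MYCT1 followed, from -0.65 to -0.54. Outside the rule, and named after their values were seen, the pseudogene UBBP4 rose by more than any of these (2.27, SE 0.42), and MRPL23, which had passed higher in HIV-1 against PBS, fell, with 414 and 423 counts in HIV-1 replicates 2 and 3 against 9 and 7 in HIV-1+LTA replicates 2 and 3. Other list members that passed were VIM (-0.31, SE 0.0824) among the stellate cell and matrix genes, PPP1R15A (-0.30, SE 0.0894) of the stress response, TP53INP1 (0.38, SE 0.109) of the p53 targets, ALDOC (0.52, SE 0.124) and BNIP3L (0.23, SE 0.0652) of the hypoxia list, and FTH1, the ferritin heavy chain (0.27, SE 0.0748). The mitochondrially encoded cytochrome oxidase genes COX1 and COX2 passed at 0.29 (SE 0.0836) and 0.30 (SE 0.0788). The mitochondrially encoded genes were lower in HIV-1 against PBS, which uses the same HIV-1 libraries, and for HIV-1+LTA against PBS none passed (median -0.02, 5 of 13 above 0, camera adjusted p 0.715), so these results are not independent.

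In all, DESeq2 with the replicate block called 179 genes higher and 65 lower, with a median absolute log2 fold change of 0.42, and 12 calls reached 2-fold. Of the 243 calls also tested in edgeR, 229 moved the same way in all batches, which a fit with the block favours. edgeR called 0 of 16117 genes, with 153 at an unadjusted p below 0.05 where 805.8 are expected if no gene changed, and DESeq2 without the block called 1. With the replicate block edgeR and limma-voom also called 0, with 2486 and 2578 genes below that p and a lowest adjusted p of 0.171 and 0.184. With batch 1 left out, DESeq2 with the block called 660 higher and 725 lower; with batch 2 left out it called 0 in either direction, and with batch 3 left out 1 higher and 0 lower.

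As sets, 6 of the 23 lists tested passed camera. Interferon-stimulated genes stood higher (35 of 38 above 0, median 0.33, camera adjusted p 5.56e-10; adjusted p = 0.149 with an estimated correlation). Their median was 0.01, 0.54 and 0.35 in batches 1, 2 and 3. HIV-1 entry and restriction factors stood higher (median 0.20, camera adjusted p 1.08e-04; adjusted p = 0.194 with an estimated correlation), with batch medians of 0.05, 0.37 and 0.14, as did mitochondrially encoded genes (13 of 13 above 0, median 0.18, camera adjusted p 1.35e-07; adjusted p = 0.194 with an estimated correlation), with 0.08, 0.27 and 0.19. TGF-beta targets stood lower (8 of 26 above 0, median -0.17, camera adjusted p 0.00124; adjusted p = 0.149 with an estimated correlation), with batch medians of -0.06, -0.24 and -0.22. Immediate early genes stood lower (median -0.14, camera adjusted p 0.0207; adjusted p = 0.149 with an estimated correlation), with -0.04, -0.05 and -0.29 by batch. Cholesterol synthesis genes stood higher (21 of 25 above 0, median 0.07, camera adjusted p 0.0334; adjusted p = 0.504 with an estimated correlation), with -0.03, 0.05 and 0.20 by batch. With the replicate block the same number of lists, 6, passed camera and none with an estimated correlation, the lowest adjusted p being 0.56. Adjusted over the list alone, 22 interferon-stimulated genes were higher in DESeq2 and 22 in edgeR, both with the block, and 0 in edgeR without it; for the TGF-beta targets 3 were lower in DESeq2 and 8 in edgeR with the block. Chemokines and cytokines (median 0.24, camera adjusted p 0.365) and NF-kB target genes (median 0.02, camera adjusted p 0.698) did not pass. Among their members IL11 was at -0.64 (SE 0.237) and MAP3K8 at 0.43 (SE 0.202), neither passing.

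**Figure D3:**
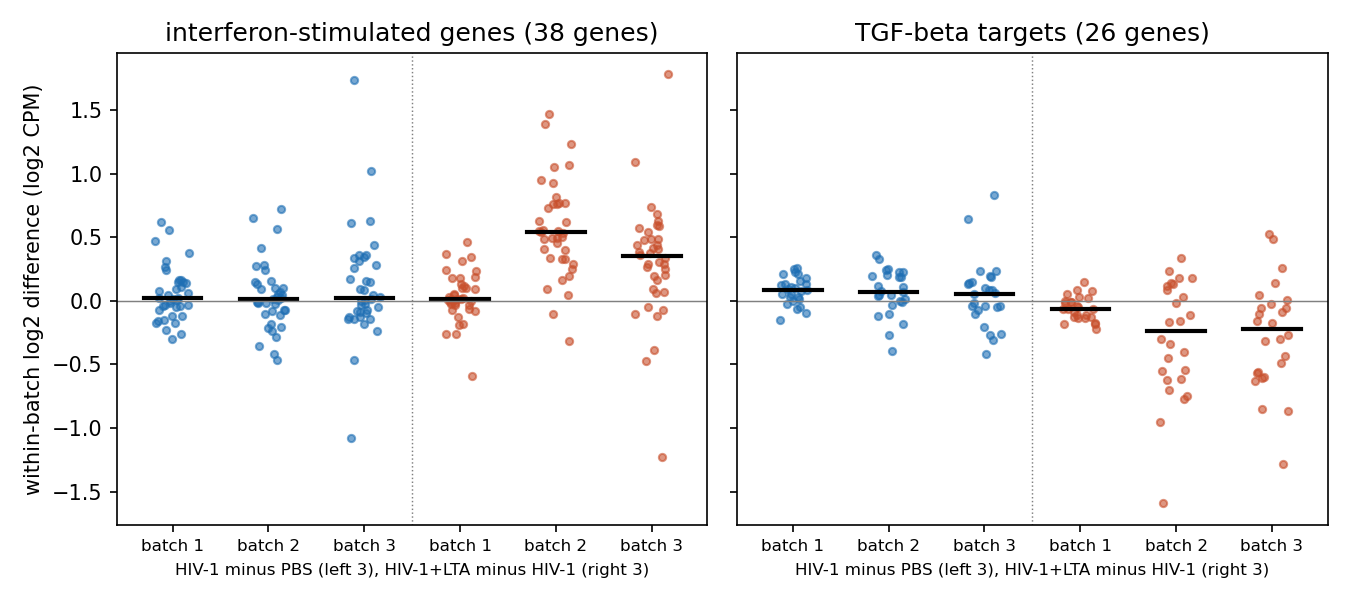
Within-batch log2 differences (log2 CPM) of 38 interferon-stimulated genes (left) and 26 TGF-beta targets (right); each point is a gene, bars are list medians, blue is HIV-1 minus PBS and orange HIV-1+LTA minus HIV-1. The interferon-stimulated medians for HIV-1+LTA minus HIV-1 are 0.01, 0.54 and 0.35 in batches 1, 2 and 3, and those of the TGF-beta targets -0.06, -0.24 and -0.22.

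The response to LTA was not alike across batches. Over 9319 genes of at least 10 CPM, the HIV-1+LTA minus HIV-1 difference correlated at r = 0.63 (rho 0.564) between batches 2 and 3, against 0.06 (rho 0.0198) between 1 and 2 and 0.09 (rho 0.0723) between 1 and 3; these are correlations across genes, which are not independent replicates. The difference exceeded 0.5 on the log2 scale for 3 genes in batch 1, 393 in batch 2 and 213 in batch 3. The p-values of single genes measure only the spread between these libraries, which may be technical. Camera sets a list's genes against other genes and Fisher's exact test counts genes, so small p-values there do not measure agreement between libraries.

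HIV-1+LTA against PBS gives the joint effect of virus and LTA. In DESeq2 with the replicate block 9 of 38 interferon-stimulated genes rose and 29 did not pass, and as a set they had adjusted p = 0.136 with an estimated correlation in camera and a median of 0.03 in batch 1. Among the 9 were PSMB9 (0.72, SE 0.137), OAS3, a sensor of double-stranded RNA (0.39, SE 0.088), IFIT3 (0.41, SE 0.1) and ISG15, a ubiquitin-like modifier (0.50, SE 0.125). The membrane restriction factors IFITM3 (0.39, SE 0.0881) and IFITM2 (0.39, SE 0.11) also rose. Of 29 activated stellate cell and matrix genes 4 fell and 25 did not pass: VCAN (-0.34, SE 0.0939), LOX, the collagen cross-linking enzyme (-0.33, SE 0.094), VIM (-0.31, SE 0.0824) and TNC (-0.29, SE 0.083) were lower. As a set these genes did not pass (median -0.04, 14 of 29 above 0, camera adjusted p 0.239). Of 25 matrix metalloproteinases and inhibitors only TIMP1 passed, higher (0.32, SE 0.0941). ACTA2 was at -0.80 (SE 0.298 in edgeR) and did not pass.

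Under the limits of the naming rule, the largest rises in that fit were MGP (1.30, SE 0.303), IFIH1, the RNA sensor MDA5 (1.00, SE 0.255), MYO7A (0.97, SE 0.218), PPL (0.88, SE 0.265) and OLFML2A (0.83, SE 0.201). SECTM1, GASK1B, PSMB9, OAS2 and TRANK1 followed, from 0.81 to 0.69. The largest falls under the same limits were PSG2 (-1.22, SE 0.288), EGF, the epidermal growth factor (-1.03, SE 0.196), SERPINB7 (-0.66, SE 0.179), NFATC2 (-0.64, SE 0.168) and NPR3 (-0.63, SE 0.129). LNCOG, GRPR, KCNQ5, FSTL3 and GFOD1 followed, from -0.56 to -0.43. Of other list members, DUSP1 (-0.46, SE 0.117), SMAD7 (-0.39, SE 0.112) and BIRC2 (-0.31, SE 0.0925) fell, EGR1 (0.42, SE 0.124), ALDOC (0.41, SE 0.123) and FTH1 (0.27, SE 0.0747) rose, and the antioxidant genes GCLM (-0.30, SE 0.0862) and PRDX1 (-0.20, SE 0.0576) fell.

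Altogether 118 genes were called higher and 118 lower in that fit, with a median absolute log2 fold change of 0.37 and 4 calls at 2-fold. Of these 236, 187 moved the same way in all batches, which the block again favours. The authors' deposited table names no comparison; its log2 fold changes and calls are those of this fit (all 19990 genes within 0.01, 236 of 236 calls shared). edgeR called 0 of 16117 genes (141 at an unadjusted p below 0.05, where 805.8 are expected if no gene changed). edgeR and limma-voom with the replicate block called 0 (2709 and 2813 below that p, lowest adjusted p 0.205 and 0.193), and DESeq2 without the block 0. The genes with the lowest p in edgeR were PSMB9 (0.74, SE 0.171), PAQR8 (0.39, SE 0.116), the cold-inducible RBM3 (-0.46, SE 0.144), FAIM2 (1.00, SE 0.317) and OAS2 (0.71, SE 0.226). With batch 1 left out, DESeq2 with the block called 567 higher and 1035 lower, with batch 2 left out 0 in either direction, and with batch 3 left out 1 higher and 0 lower.

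By camera, 4 lists passed for HIV-1+LTA against PBS. Interferon-stimulated genes stood higher (35 of 38 above 0, median 0.35, camera adjusted p 5.84e-12; adjusted p = 0.136 with an estimated correlation), with 0.03, 0.59 and 0.44 in batches 1, 2 and 3. HIV-1 entry and restriction factors (20 of 23 above 0, median 0.14) and chemokines and cytokines (17 of 21 above 0, median 0.39) each had a camera adjusted p of 0.00691, and adjusted p = 0.464 with an estimated correlation. Their batch medians were 0.02, 0.32 and 0.12, and 0.02, 0.45 and 0.15. Cholesterol synthesis genes stood higher (19 of 25 above 0, median 0.11, camera adjusted p 0.0256; adjusted p = 0.539 with an estimated correlation), with batch medians of 0.07, 0.05 and 0.18. Immediate early genes (median -0.04, camera adjusted p 0.592), TGF-beta targets (median -0.10, camera adjusted p 0.0903) and the mitochondrially encoded genes passed for HIV-1+LTA against HIV-1 but not here; the HIV-1 libraries of that comparison are also those of HIV-1 against PBS. With the replicate block, Toll-like receptor signalling (median 0.08) and replication-dependent histone genes (median 0.08) also passed camera, higher, each at an adjusted p of 0.0457; with the block and an estimated correlation each had an adjusted p = 0.669. Adjusted over the list alone, 26 interferon-stimulated genes were higher in DESeq2 with the block, 28 in edgeR with it and 0 in edgeR without it.

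Genes called in both LTA comparisons numbered 67 higher and 30 lower in DESeq2 with the replicate block, among 12239 genes tested in both. Independent lists would share 1.73 and 0.627, but these comparisons share their HIV-1+LTA libraries, so such an overlap is no separate evidence. HIV-1 against PBS and HIV-1+LTA against PBS share the PBS libraries: their log2 fold changes correlated at r = 0.313 (rank correlation 0.319) across 9321 genes. Simulations with no effect and shared PBS libraries gave a mean r of 0.495 (0.473 to 0.524, 50 simulations). Their spread per gene was estimated over all 9 libraries, the uneven LTA response included, so this r is not a firm reference. The covariance was 0.00337, inside the range of the simulations (mean 0.0031, 0.0029 to 0.00357). No shared effect beyond the shared controls could be shown.

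TLR2 and CXCR4 were scarce in these cells; the genes of this paragraph were chosen after their values were seen. CXCR4, a chemokine receptor, had 1 to 16 counts per library. CD4 was at 12.8 to 18.2 CPM in batches 1 and 2 and 1.36 to 2.43 CPM in batch 3. TLR2, the receptor of LTA, had 1 to 49 counts per library (0.02 to 0.523 CPM), while TLR4 had a mean of 67.6 CPM. CD14 was at 2.34 to 9.72 CPM. The interferon genes IFNB1 and IFNL1 had 0 counts in all 9 libraries.

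Markers of other cell types did not pass as sets in any comparison. For HIV-1+LTA against HIV-1 the camera adjusted p was 0.365 for T cell markers (6 measured), 0.796 for myeloid markers (8 measured) and 0.796 for endothelial markers (12 measured); for HIV-1 against PBS it was 0.156, 0.802 and 0.362, and for HIV-1+LTA against PBS 0.888, 0.715 and 0.7. Of the hepatocyte markers only 2, SERPINA1 and ASGR1, were measured, at means of 1.2 and 1.82 CPM, too few for a test. Proliferation genes did not pass either (camera adjusted p 0.864, 0.459 and 0.608 in the order HIV-1 against PBS, HIV-1+LTA against HIV-1, HIV-1+LTA against PBS). In the same order, HIV-1 dependency factors were at 0.701, 0.358 and 0.207, matrix metalloproteinases and inhibitors at 0.417, 0.617 and 0.278, and the integrated stress and unfolded protein response at 0.363, 0.268 and 0.715. The p53 target genes were at 0.746, 0.117 and 0.0811, hypoxia and glycolysis genes at 0.365, 0.495 and 0.96, and NRF2 oxidative stress genes at 0.746, 0.973 and 0.866.

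The HIV-1 ChIP-seq peaks lay at gene starts far more often than random placement gave. The list has 166 lines and 154 distinct intervals, 181 to 430 bp wide (median 222.5 bp), covering 37152 bp of hg19. Of these, 75 lay within 1 kb of a transcription start of a protein-coding gene, where random placement on the same chromosomes gave a mean of 2.31 and at most 8 in 100 sets. Another 8 lay in exons, 40 in introns and 31 outside protein-coding genes. Their median GC content was 62.5%, against 52.65% in the 1000 bases on each side. The random placements had a median GC content of 40.3% and were not matched to the peaks for it. They therefore cannot tell a preference for gene starts from one for GC-rich sequence. There was 1 library and no replicate, the list gives no value per peak, and no PBS list was used here, so peaks were not compared between treatments.

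**Figure D4:**
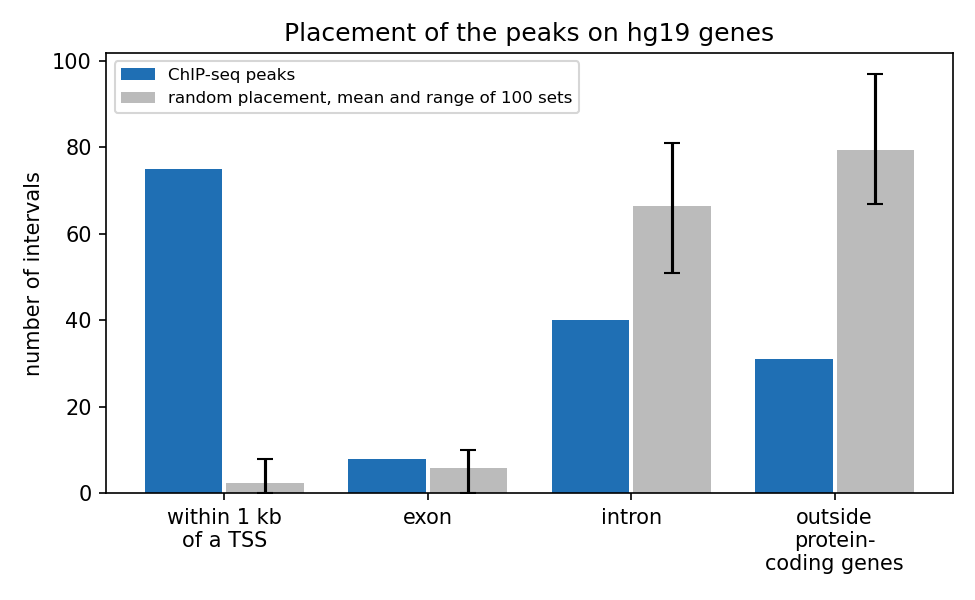
Number of the 154 distinct HIV-1 ChIP-seq intervals (blue) by place on hg19 protein-coding genes, beside random placement (grey, mean of 100 sets with lowest to highest as error bars). Within 1 kb of a transcription start lie 75 peaks, against a mean of 2.31 by random placement, which was not matched for GC content.

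Genes of the fixed lists within 10 kb of a peak included 1 of 40 interferon-stimulated genes and 1 of 27 TGF-beta targets. Of all protein-coding genes tested, 173 of 13917 lay as near. Whether the lists differ from that share was not tested. A peak of 194 bp lay 418 bp from the start of XAF1 (chromosome 17, 6659087 to 6659280) and another 248 bp from that of LGALS3BP (chromosome 17, 76976181 to 76976372), a secreted glycoprotein induced by interferon. In all, 11 list genes lay within 10 kb of a peak: IRF1, XAF1, TASOR, PDGFRB, TGIF1, DUSP7, MANF, KIF11, GAPDH, RPL14 and RPS19. The peak nearest SMAD7 was 39613 bp from its start (chromosome 18, 46516821 to 46517074), and 2 peaks lay 96412 and 100432 bp from that of SMAD6, another inhibitor of the pathway. No peak lay within 50 kb of CXCL8. The only peak on its chromosome, near TMEM129, was 72.9 Mb away. With 154 intervals in the whole genome, this distance says little about CXCL8 itself. In total 135 peaks lay within 10 kb of a protein-coding gene, 199 genes in all, 173 of them among 13917 protein-coding genes tested. edgeR called 0 genes in HIV-1 against PBS, so the planned Fisher's exact test had nothing to count. For the calls of DESeq2 with the replicate block, 2 of 229 protein-coding genes called in HIV-1+LTA against HIV-1 lay near a peak (FBLN2 and LGALS3BP, odds ratio 0.696, two-sided Fisher's exact p = 1), and 4 of 225 in HIV-1+LTA against PBS (FBLN2, LGALS3BP, MBNL1 and ROMO1, odds ratio 1.45, two-sided Fisher's exact p = 0.365).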

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

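The alternatives with DESeq2 or limma-voom and the replicate block, and those that leave out a whole batch, were chosen after the data were seen; the others were set beforehand. The counts of 0 genes in edgeR held under the other scalings and filters, the replicate block in edgeR, limma-voom with and without the block, the 6-library fits, the fold limit and leaving out any 1 library. DESeq2 without the block called 1 gene higher for HIV-1 against PBS and 1 lower for HIV-1+LTA against HIV-1. DESeq2 with the replicate block called 1 higher and 2 lower, 179 and 65, and 118 and 118, for HIV-1 against PBS, HIV-1+LTA against HIV-1 and HIV-1+LTA against PBS. Pairing changed no call other than these and those of the lists named in the report and, for lists added later, in the observations. The lists passing camera, 4, 6 and 4, became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry, which asks another question.

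The DESeq2 counts with the block rest on batches 2 and 3. With batch 1 left out they were 11 higher and 35 lower, 660 and 725, and 567 and 1035 in the same order. With batch 2 left out they were 0 and 0 in each comparison, and with batch 3 left out 0 and 0, 1 and 0, and 1 and 0. Leaving out 1 library at a time gave 0 to 8 higher and 0 to 14 lower for HIV-1 against PBS (8 and 14 without PBS replicate 1), 0 to 975 and 0 to 1133 for HIV-1+LTA against HIV-1 (highest without HIV-1+LTA replicate 1), and 0 to 926 and 0 to 1493 for HIV-1+LTA against PBS (highest without HIV-1+LTA replicate 1). For HIV-1+LTA against HIV-1 the counts were 244 and 124 without HIV-1 replicate 1, 0 and 0 without HIV-1 replicate 2, 2 and 0 without HIV-1 replicate 3, 2 and 3 without HIV-1+LTA replicate 2, and 5 and 4 without HIV-1+LTA replicate 3. For HIV-1+LTA against PBS they were 205 and 397 without PBS replicate 1, 0 and 0 without PBS replicate 2, 3 and 1 without PBS replicate 3, 0 and 2 without HIV-1+LTA replicate 2, and 1 and 3 without HIV-1+LTA replicate 3. Fewer libraries alone lower such counts; the rise without batch 1 has no tested cause.

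CXCL8 for HIV-1 against PBS reversed in 1 setting, to -0.0836 in DESeq2 with the block and batch 2 left out; over the settings with all libraries or whole batches left out it ran from there to 0.37, and leaving out 1 library gave 0.05 to 0.33. CXCL8 ran from 0.19 to 0.56 for HIV-1+LTA against HIV-1 and from 0.40 to 0.77 for HIV-1+LTA against PBS when 1 library was left out. In edgeR without the block, leaving out a library unbalances the batches and reversed some named genes, none of which passes in that fit. For HIV-1+LTA against HIV-1 the log2 fold change ran from -0.65 to 2.64 for GNG7, -3.26 to 1.19 for DAW1, -2.12 to 0.63 for KCNQ5, -1.75 to 0.54 for BCYRN1, -2.06 to 0.86 for XYLT1, -1.32 to 0.15 for NPR3, -3.69 to 2.60 for MYCT1 and -1.31 to 0.70 for VIM. For HIV-1+LTA against PBS it ran from -3.87 to 1.42 for PSG2, -1.35 to 0.0397 for NPR3, -1.20 to 0.15 for LNCOG, -1.68 to 0.62 for GRPR, -1.89 to 0.81 for KCNQ5, -0.80 to 0.22 for BIRC2, -1.32 to 0.73 for VIM and -1.96 to 1.29 for LOX. The lowest values came without HIV-1+LTA replicate 3, the highest without the batch 3 library of the other group. Reversals to values near 0 also came without HIV-1+LTA replicate 2 (MYCT1 and VIM against HIV-1; KCNQ5, VIM and LOX against PBS) and without HIV-1+LTA replicate 1 (MYCT1 against HIV-1, LOX against PBS). Other named genes kept their direction but came within 0.1 of 0. Against PBS, GASK1B came to 0.00952 and SECTM1 to 0.07 without HIV-1+LTA replicate 2, OAS3 to 0.07 and TIMP1 to 0.0018 without PBS replicate 3, where NFATC2 was at -0.10, PRDX1 at -0.06, TNC at -0.05 and GCLM at -0.012, and VCAN was at -0.09 without HIV-1+LTA replicate 3. For HIV-1 against PBS, IGFBP5 was at -0.06 without PBS replicate 2. Further named genes moved by more than 1.5 times, the largest rises among them. Against HIV-1 these were DTNA (0.78 to 1.76), MGP (0.62 to 1.68), GASK1B (0.49 to 1.51), CLCA2 (0.15 to 1.52) and PPL (0.34 to 1.43). Against PBS they included MGP (0.67 to 1.63), PPL (0.14 to 1.23) and IFIH1 (0.26 to 1.30).

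The correlation of effects that share the PBS libraries was 0.313, and 0.512 with batch 2 left out; the cause was not tested. Genes near peaks numbered 199 within 10 kb and 405 within 50 kb, where the wider window takes in more genes. A stricter peak threshold was not run, since the list gives no value per peak. At 50.6 M counts or more per library, depth limits genes such as CXCR4 and TLR2, with at most 49 counts, more than the abundant genes.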

Other observations

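The lists of this part, its tests of batches and of peak sequence were chosen after the results were seen, except for the splits of the libraries and the test of GC content and gene length, which were set beforehand. Ribosome biogenesis and chaperone genes stood lower with HIV-1+LTA than with HIV-1, while cytosolic ribosomal protein genes (median -0.00405, camera adjusted p 0.796) and proliferation genes (median 0.02, camera adjusted p 0.459) did not pass. Of 40 ribosome biogenesis genes 5 fell in DESeq2 with the replicate block (PES1, BYSL, RRP12, MRTO4 and WDR43), with list medians of -0.02, -0.37 and -0.24 in batches 1, 2 and 3 (camera adjusted p 1.03e-12; adjusted p = 0.113 with an estimated correlation). Of 28 chaperone genes 3 fell in the same fit, HSP90AB1, HSPH1 and FKBP4, with medians of -0.02, -0.32 and -0.18 (camera adjusted p 7.95e-06; adjusted p = 0.113 with an estimated correlation). Of 21 genes of MHC class I antigen presentation 2 rose, the proteasome genes PSMB9 and PSME1, with medians of 0.00237, 0.49 and 0.17 (camera adjusted p 4.12e-05; adjusted p = 0.113 with an estimated correlation). For HIV-1 against PBS, which shares the HIV-1 libraries, the ribosome biogenesis and chaperone lists stood higher with the replicate block in camera (adjusted p 0.0285 and 0.0284; adjusted p = 0.799 each with the block and an estimated correlation) and did not pass without it (adjusted p 0.215 and 0.434). These lists were written after the called genes had been seen and are no independent evidence. For HIV-1+LTA against PBS in the DESeq2 fit, NPM1, GNL3 and DDX21 of the first list fell; of the chaperones HSP90AB1 and CCT5 fell and HSPB1 rose; HLA-F, PSMB9 and PSMB10 of the last list rose.

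Batch 3 differed from batches 1 and 2 across much of the transcriptome, with the 3 groups pooled. In edgeR 5669 genes were higher and 5809 lower in batch 3, 1294 and 1774 of them at least 2-fold, while batch 2 against batch 1 gave 5 higher and 0 lower. No fixed list passed camera for batch 3 (lowest adjusted p 0.25). By fry, which compares a list with no other genes, most lists passed, whatever their theme. Lists that stood lower included Toll-like receptor signalling (adjusted p 0.000403), histone genes (adjusted p 0.00173) and chemokines and cytokines (adjusted p 0.00945). HIV-1 entry and restriction factors (adjusted p 0.00975) and NF-kB target genes (adjusted p 0.0349) were lower too. Of the NF-kB target genes, however, 10 were called higher and 11 lower. Lists that stood higher included hypoxia and glycolysis genes (adjusted p 0.0037) and cytosolic ribosomal protein genes (adjusted p 0.0114). With so many genes differing in batch 3, passing fry marks no particular process. The single genes given here were chosen after their values were seen. DIO2, which activates thyroid hormone, was at 94.5, 84.4 and 0.655 CPM in batches 1, 2 and 3, the neuronal gene RTN1 at 41.5, 45 and 0.897 CPM, the matrix protease MMP2 at 132, 126 and 8.94 CPM, and the desmosome gene DSP at 68.1, 64.2 and 3.27 CPM. In the other direction SEMA3A was at 3.29, 3.88 and 161 CPM, CYP24A1, which degrades vitamin D, at 4.61, 5.57 and 197 CPM, COL1A2, a chain of type I collagen, at 36.9, 34.8 and 288 CPM, and LOX at 145, 161 and 1110 CPM. PTGS2 had 33 to 91 counts in each library of batches 1 and 2 and 0 in each of batch 3. The pseudogene UBBP4 had 208 and 242 counts in HIV-1+LTA replicates 1 and 2, 30 in replicate 3, and 19 to 44 in the PBS and HIV-1 libraries.

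HIV-1+LTA differed from HIV-1 in batches 2 and 3 and hardly in batch 1. HIV-1 minus PBS was also flattest in batch 1, exceeding 0.5 on the log2 scale for 2 genes, against 17 and 37 in batches 2 and 3. Library pairs differed by 2.83 to 3.29 times counting noise in batch 1, 6.31 to 18 in batch 2 and 6.4 to 13.1 in batch 3. All 3 libraries of batch 1 were thus more alike, not only the one with LTA. Swapped labels within batch 1 and lower depth are argued against: no library of that batch carried the batch 2 and 3 profile, the slope of largest size being -0.0341, where a swap needs 0.5 or more, and the shallower of the 2 libraries held 55.2 M counts, more than the shallowest in batch 3 (50.6 M). An HIV-1+LTA replicate 1 culture or library that never received LTA, and a treated culture that did not respond, remain open and cannot be told apart: both may give the slope near 0 that was seen, 0.0323, against 0.76 and 0.522 between batches 2 and 3. Single values that go with a treated culture are UBBP4, with 208 counts in HIV-1+LTA replicate 1 against 30 in HIV-1 replicate 1, and CXCL8, higher by 0.62 (log2 CPM) in batch 1. UBBP4 also had 242 counts in HIV-1+LTA replicate 2 against 21 in HIV-1 replicate 2. In batch 3, where HIV-1+LTA did differ, UBBP4 had 30 against 25 counts and CXCL8 was at -0.01. Neither gene therefore marked the treatment in every batch, and whether they mark it in batches 1 and 2 was not tested. No biological explanation was tested, since the labels give no difference between the batches.

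Batch 3 stood apart in all 3 groups. GC content and gene length explained 0.983% of the variance of the difference across the 15699 genes with both values. Of the 2945 genes with 2-fold calls among these, 2703 kept their call after that trend was removed, which argues against such a bias. A minor share of cells of another type is argued against as the only cause, with the line's own cells unchanged: it would dilute their transcripts by less than 2 times, yet 14 of 7390 abundant genes were lower by 8 times or more. Such a share beside a change in the line's own cells stays open. A different passage, stock or clone of cells, another cell line, or another library preparation may be behind it and was not tested, and another line would change what every mean over the 3 batches describes; no biological explanation was tested, since the labels name the same line for all 9 libraries.

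A consensus site of NF-kB, the factor that drives CXCL8, was more frequent in the peaks than beside them, in 25 of 153 peaks with sequence (16.3%) and 12 of 306 flanking windows (3.92%). Base composition may account for it: sequences drawn from each peak's own dinucleotides matched in 27.8 peaks on average (19 to 40), and 159 of 200 draws matched at least as often as the peaks. No biological explanation was tested, since the antibody is not given.

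The splits of the libraries are too few for a share under 0.05. In edgeR all 10 of 10 splits in each comparison called 0 genes, as the real one did. For lists passing camera, counting the real split, 3 of 10 splits gave as many for HIV-1 against PBS (real 4, highest other 5), 2 for HIV-1+LTA against HIV-1 (real 6, highest other 7) and 3 for HIV-1+LTA against PBS (real 4, highest other 6). Most of these splits mix libraries of different batches. Among those within batches, the split that exchanges the libraries of batch 1 gave 5, 7 and 4 lists in the same order, at least as many as the real one. The other within-batch splits gave fewer than the real one, except 6 for HIV-1+LTA against PBS with the libraries of batch 3 exchanged. With DESeq2 and the replicate block, 1 of the 4 splits within batches, the real one, gave the most genes each time: 3 (highest other 1), 244 (highest other 11) and 236 (highest other 228). The 228 came from the split that exchanges PBS replicate 1 with HIV-1+LTA replicate 1.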
